A study of Glycine max with 4 samples.

How the data were processed

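Messenger RNA of soybean (Glycine max) roots was sequenced in 4 libraries, 2 from wild-type plants (WT) and 2 from transgenic plants in which GmHAD1-2 was suppressed (Ri, the submitters' own short name for the line). Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with a BGI RNA-Seq kit. The design text gives 12 days in nutrient solution with KH2PO4 at 250 mM (unit as stated there, which is in doubt because nutrient solutions usually hold micromolar phosphate) before the roots were taken, and calls the libraries of each genotype biological replicates. Neither the number of plants behind a library nor a growth, library or sequencing batch was given in the sources used here.

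The authors deposited 1 table per library. Per the file headers, each gives a gene identifier, its transcripts, a length, an expected count and an FPKM value (fragments scaled by transcript length and by depth). The deposited expected counts are estimated numbers of fragments per gene that need not be whole, as arises when a fragment that matches several genes is divided among them, and they are not normalized. The FPKM values were made by the authors from those estimates, the length and the depth. Bowtie2, HISAT and RSEM are named in the submitters' processing notes. Their roles, versions and settings, any trimming, and whether strand was used in counting are not given in the sources used here. The identifiers end in Wm82.a2.v1, the second assembly of the cultivar Williams 82. A table lists only genes with a value above 0: the lowest listed FPKM was 0.01, and the largest expected count at that FPKM was 1, so an unlisted gene was taken as 0. No row lacked a gene and no identifier was repeated.

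The deposited totals of expected counts were 10713625, 10686759, 10077854 and 11070260 in WT replicate 1, WT replicate 2, Ri replicate 1 and Ri replicate 2, and 47973 genes were listed in at least 1 library. At this depth 3 counts correspond to 0.264 to 0.306 CPM (counts scaled to library size, as in edgeR), the level taken as the floor of a library. Intervals and floors cover counting error only.

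No gene could be named. The reference table used here holds 59048 genes of another assembly (Glycine_max_v4.0), and 0 of the 47973 identifiers matched its gene, locus, symbol, synonym or accession fields. The 35 gene lists and the product-name families that had been fixed before the data were examined depend on product names and were therefore not tested, and this includes the lists of markers of other root cell types. For the same reason GmHAD1-2 and the protein phosphatase genes of the series' title are not analysed here. The suppression of GmHAD1-2 in the Ri libraries therefore rests on the labels and could not be checked. At most 2 identifiers are printed per direction: the 2 genes past the threshold with the largest decrease, with replicate values that do not overlap and at least 5 CPM in the higher group, and the 2 rises with the smallest p, given as not significant. This keeps the rule fixed beforehand except for its product-name condition. A chromosome is the number that the identifier carries, and coordinates are not used here.

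The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on expected counts rounded to whole numbers, with TMM scaling, edgeR's default filter on low counts (34151 genes kept), robust estimation and genotype as the only term. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Standard errors of log2 fold changes were computed as the fold change divided by the square root of the F statistic. CPM values and floors use the TMM-scaled library sizes, except for the 1 CPM limit and the CPM of genes listed in 1 genotype or 1 library only, which were chosen on unscaled totals; their fold bounds and group means use the scaled sizes. The alternatives were other scalings, DESeq2 1.42.0, limma 3.58.1 on voom values and on log2(FPKM + 1) or log2(FPKM + 0.1) of the deposited FPKM, other filters and thresholds, a gene-length correction (loess, span 0.3), the replicate number as a block, and each library left out in turn.

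The fits were tested on simulated data with the real means and, for each gene, 1 spread shared by both genotypes. Counts were drawn for the 34151 genes kept by the filter, with 200 genes of at least 5 CPM changed. On the simulated counts edgeR's filter kept 33576 genes. In the real libraries the Ri replicates differed more than the WT replicates (SD of the log2 difference 0.59 against 0.31, genes of at least 8 CPM). The shares recovered therefore need not hold for the real libraries. In the edgeR test 32 of 33 falls of 8-fold, 22 of 33 of 4-fold and 3 of 33 of 2-fold were recovered. Of the simulated rises, 33 of 33 of 8-fold, 33 of 34 of 4-fold and 6 of 34 of 2-fold were recovered, and 18 unchanged genes were called. Unchanged genes thus made up a larger share of edgeR's simulated calls than the adjusted p threshold is meant to allow. The same held for DESeq2 on these counts. The calls of either test in the real libraries may therefore hold more false ones than the threshold implies. On the same simulated counts DESeq2 called 31 unchanged genes (34151 genes in its step), and edgeR without Ri replicate 1 called 83 (33957 genes).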

Results

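The transcriptomes of soybean roots were compared between wild-type plants and plants with suppressed GmHAD1-2, both supplied with phosphate. GmHAD1-2 is named after the haloacid dehalogenase (HAD) superfamily, which holds many phosphatases. The single comparison of the design, Ri against WT with n = 2 libraries each, addresses which root transcripts differ in the line labelled as suppressed. The suppression itself was not checked. The libraries held 10077854 to 11070260 expected counts in total. WT replicates 1 and 2 listed 42304 and 41921 genes above 0, and Ri replicates 1 and 2 listed 44830 and 42618. Genes of at least 1 FPKM numbered 31636 to 32535 per library. The 10 most abundant genes took 4.19% to 4.42% of each library's counts.

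In Ri roots 40 genes were lower than in WT roots and 0 were higher, among 34151 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05, edgeR gave 1317 lower and 818 higher genes, 2135 in all, where 1708 would be expected from evenly spread p-values. The other ways of dividing the libraries into pairs gave 464 and 2667 such genes. The excess over 1708 can therefore not be credited to genotype. DESeq2 called 265 lower and 36 higher genes, and its 301 calls included all 40. By contrast, limma-voom, limma on FPKM and edgeR on library totals called 0 genes, and edgeR with upper-quartile factors called 12. The 40 decreases were large. Their median log2 fold change was -3.19 (SD 0.82 over the 40 genes), a 9.14-fold decrease, and they ran from 3.56-fold to 65.8-fold. All 40 fell by more than 2-fold, 38 by more than 4-fold and 26 by more than 8-fold. In each of the 40 genes both Ri values lay below both WT values. The genes were of moderate abundance in WT, with mean levels from 8.61 to 421 CPM and a median of 37.9 CPM, and their median in Ri was 3.65 CPM. Summed over the 40 genes, expression was 2453 and 1902 CPM in the WT libraries and 304 and 285 CPM in the Ri libraries, a 7.39-fold lower sum in Ri. Only 2 of the 40 had whole expected counts in every library (within 0.005), against 4557 of the 34151 tested genes (13.3%). The values of the other 38 are therefore uncertain to the extent that fragments were divided among similar genes. The number of calls depended on single libraries. It was 0 without WT replicate 1 and 0 without WT replicate 2 (795 and 991 genes at an unadjusted p under 0.05), 1994 without Ri replicate 1 (1151 higher) and 1623 without Ri replicate 2 (634 higher), with the lone library assumed to vary like the others. The fold changes of all 40 genes stayed below 0 in all 4 of these fits, which their lack of overlap between genotypes made all but certain.

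**Figure D1:**
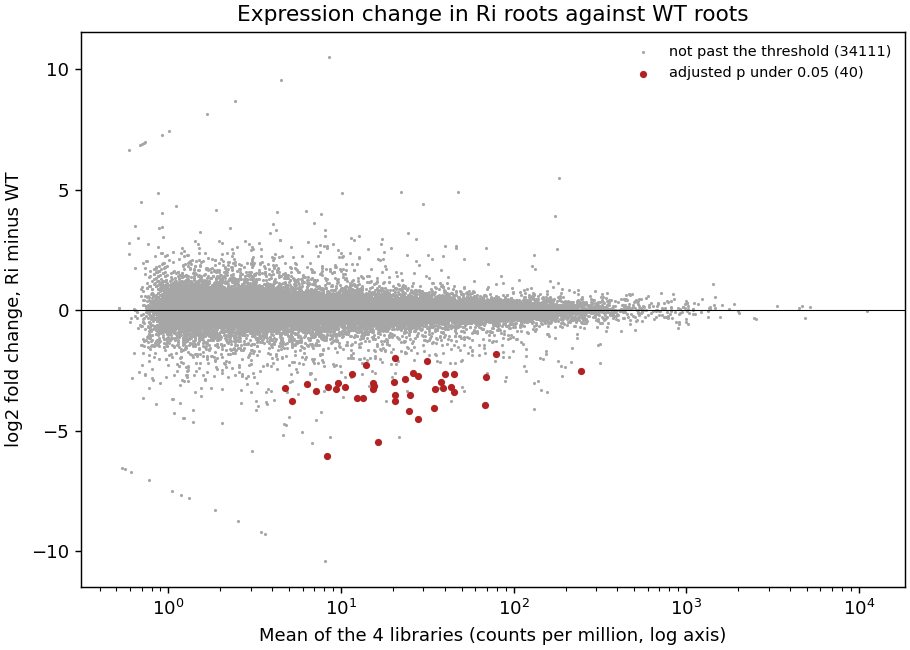
Each point is 1 of the tested genes, with its mean level over the 4 libraries on a log axis (CPM) against its log2 fold change, Ri minus WT. The 40 genes past the threshold (red) all lie below 0, and grey points, including those with the largest positive values at low levels, did not pass.

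The largest decrease was that of Glyma.02G189700.Wm82.a2.v1, a gene of chromosome 2. Its level was 16.4 CPM ± 2.20 (SD, n = 2) in WT and 0.241 CPM ± 0.092 (SD, n = 2) in Ri. Its log2 fold change was -6.04 with a standard error of 0.38 and an edgeR adjusted p of 0.0292. The decrease rests on 3 and 1.9 expected counts in the Ri libraries against 161 and 186 in WT, and the ratio of pooled counts, 69.1-fold, had an exact 95% binomial interval of 29.3 to 214. Glyma.02G203500.Wm82.a2.v1, also on chromosome 2, was at 32.3 CPM ± 0.921 (SD, n = 2) in WT and 0.730 CPM ± 0.410 (SD, n = 2) in Ri. Its log2 fold change was -5.47 with a standard error of 0.35 and an edgeR adjusted p of 0.0292. The pooled counts gave a 45.5-fold ratio, with an exact 95% binomial interval of 27.4 to 81.8. Without WT replicate 1 and without WT replicate 2 both genes lost the call, with edgeR adjusted p of 0.225 and 0.102. The log2 fold changes stayed about as large, at -6.17 and -5.88 for Glyma.02G189700.Wm82.a2.v1 and -5.50 and -5.43 for Glyma.02G203500.Wm82.a2.v1. Over the alternatives with all 4 libraries the lowest adjusted p was DESeq2's, 4.7e-12 for Glyma.02G189700.Wm82.a2.v1 and 7.0e-23 for Glyma.02G203500.Wm82.a2.v1. The highest was 0.139 for both, with limma on unfiltered log2(FPKM + 1).

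**Figure D2:**
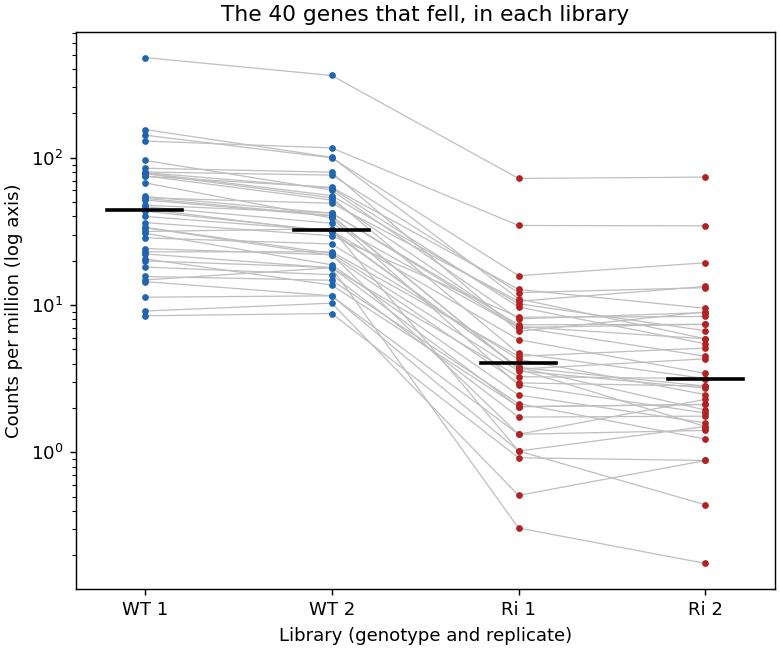
The 40 genes past the threshold in each of the 4 libraries, in CPM on a log axis; each point is a gene, grey lines join the values of a gene, and black bars are medians. The medians were 44.1 and 32.4 CPM in WT replicates 1 and 2 and 4.03 and 3.17 CPM in Ri replicates 1 and 2.

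No increase passed the threshold in edgeR with TMM scaling, its default filter and genotype as the only term, which gave 818 at an unadjusted p under 0.05, and 36 passed in DESeq2. The increase with the smallest p was that of Glyma.16G211200.Wm82.a2.v1 on chromosome 16, at 12.5 CPM ± 2.93 (SD, n = 2) in WT and 55.1 CPM ± 6.82 (SD, n = 2) in Ri. Its log2 fold change was 2.14 with a standard error of 0.23 and an edgeR adjusted p of 0.0540. Next came Glyma.18G227000.Wm82.a2.v1 on chromosome 18, which had 0 counts in both WT libraries and 113 and 74.4 expected counts in Ri replicates 1 and 2. Its mean of 9.02 CPM in Ri was at least 31.2-fold above the floor of 3 counts per WT library, with an edgeR adjusted p of 0.0647. With DESeq2 size factors in edgeR Glyma.16G211200.Wm82.a2.v1 passed, at an adjusted p of 0.0494. DESeq2 called both genes, at adjusted p of 6.9e-09 and 3.3e-06 in that order. Neither passed in limma-voom or in limma on FPKM, where the highest adjusted p were 0.170 and 0.304. Neither passed in edgeR with library totals, upper-quartile factors, the stricter filter, the length trend removed or robust estimation off. Without Ri replicate 1 and without Ri replicate 2 the log2 fold changes were 2.02 and 2.26 for Glyma.16G211200.Wm82.a2.v1. For Glyma.18G227000.Wm82.a2.v1 they were 9.15 and 9.90.

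Counted without a model, large decreases again outnumbered large increases. Among the 20248 genes of at least 8 CPM, 174 were more than 2-fold lower in both Ri libraries than in either WT library and 17 were more than 2-fold higher. Over all 34151 tested genes, low ones included, the numbers were 421 and 159. Among genes of at least 8 CPM, the other 2 ways of dividing the 4 libraries into pairs separated 3 and 20 genes by this rule. Without a requirement on size, 35.5% of these genes had no overlap between genotypes, and 33.3% is the share that chance gives for 2 libraries against 2.

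Decreases recurred between independent pairs of libraries more often than increases. Of 170 genes (at least 8 CPM) more than 4-fold lower in Ri replicate 1 than in WT replicate 1, 54.7% were more than 2-fold lower in Ri replicate 2 than in WT replicate 2, against 2.24% of all genes. Over the 4 ways of choosing the first pair, this share ran from 54.7% to 89.9% for decreases, against 2.00% to 4.08% of all genes. For increases it ran from 10.4% to 32.4%, from 28 to 67 genes chosen, and was also above the 0.617% to 2.11% of all genes. For the increases chosen in Ri replicate 2, however, the median log2 difference in the pair with Ri replicate 1 was below 0, at -0.31 and -0.35.

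The Ri libraries differed from each other more than from WT. Over genes of at least 8 CPM the SD of the log2 difference was 0.31 between the WT replicates and 0.59 between the Ri replicates, and between 0.47 and 0.56 for the 4 pairs of a WT and a Ri library. Changes of more than 2-fold separated the Ri replicates for 1296 genes (6.40%) and the WT replicates for 144 genes (0.711%). Ri replicate 1 was more than 2-fold below the 3 other libraries for 243 genes and above them for 44, whereas Ri replicate 2 was below for 87 and above for 217. In 603 genes Ri replicate 1 lay below and Ri replicate 2 above both WT libraries, with more than 2-fold between them, and in 271 genes the order was opposite. When WT replicate 1 and Ri replicate 2 were set against WT replicate 2 and Ri replicate 1, edgeR called 0 genes but gave 2667 at an unadjusted p under 0.05, more than the 2135 of the comparison by genotype. The remaining split gave 0 calls, with 464 genes at an unadjusted p under 0.05.

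Ri replicate 1 also listed the most genes found in no other library, 2747, against 549 and 437 in WT replicates 1 and 2 and 654 in Ri replicate 2. Of these, 160 reached at least 1 CPM in Ri replicate 1, against 4, 3 and 7 in the other libraries.

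**Figure D3:**
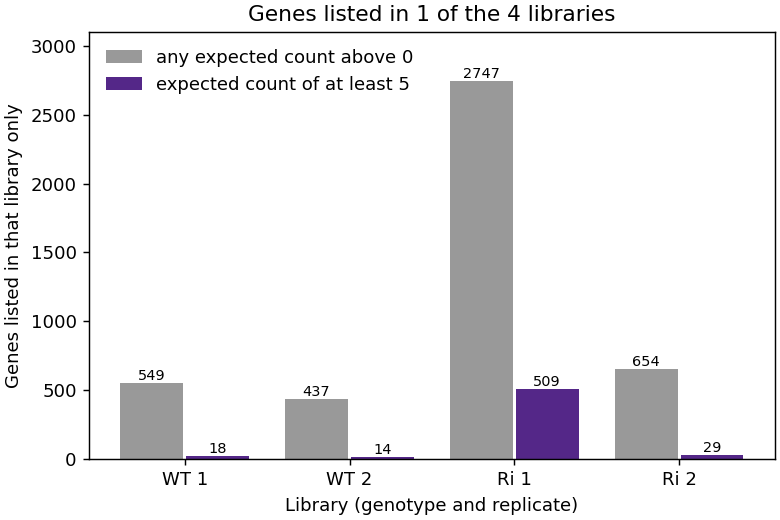
Number of genes listed in 1 library and in no other, per library. Grey bars count any expected count above 0 and purple bars an expected count of at least 5, of which Ri replicate 1 had 509 and the other libraries 14 to 29.

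A small group of genes was listed in 1 genotype only. In both Ri libraries 11 genes reached at least 1 CPM with 0 counts in both WT libraries, and 10 genes showed the reverse. The 11 genes were at least 4.08-fold to at least 59.0-fold above the floor of 3 counts per library, with a highest mean of 17.0 CPM. The 10 genes of WT were at least 3.996-fold to at least 52.9-fold above it, with a highest mean of 16.2 CPM. Among these 21 genes edgeR called 0, all 21 had an unadjusted p under 0.05, and DESeq2 called 13. The genes were chosen for this pattern in the same libraries, so a small unadjusted p was nearly built in. The other 2 ways of pairing the libraries gave 0, 0, 3 and 1 such genes. The 11 genes lay on 7 chromosomes and the 10 on 8.

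The 40 genes that fell lay on 16 chromosomes, and chromosome 2 held the most. It carried 8 of them where 2.26 were expected from the tested genes (two-sided Fisher's exact test p = 0.0015, adjusted p = 0.0308 over 20 chromosomes). Among the 8, Glyma.02G203500.Wm82.a2.v1 and another gene carry consecutive identifiers. Fisher's test counts such neighbours as independent, and it was not repeated with them counted once. No other chromosome passed, and chromosome 20 came next with 4 genes against 1.76 expected (adjusted p = 0.765). In the alternatives calls in both directions were counted together. An excess of decreases alone was therefore not tested where increases were also called. The excess on chromosome 2 passed in 9 of 12 alternatives, whose calls overlap with the 40, so these passes are not separate evidence. It did not pass without Ri replicate 1 (1.02 times the expected number), without Ri replicate 2 (1.21 times) or in 1 further alternative (2.61 times), and without either WT library there were 0 calls to place. Of the 174 genes with more than 2-fold separation, at most 3 lay within 20 neighbouring tested genes, and 489 of 1000 random placements gave as many (permutation p = 0.49). Directly neighbouring pairs numbered 3 where 0.896 were expected (permutation p = 0.06).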

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

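The test of the depth of Ri replicate 1 was chosen after the result was seen, and the 2 tests of an even background were written before their results. Ri replicate 1 listed 2747 genes that no other library listed, against 549, 437 and 654 genes for WT replicate 1, WT replicate 2 and Ri replicate 2. A gene listed in 1 library cannot pass the filter of the test, so these genes lie outside the comparison by genotype, and their number is given here for that reason and because it exceeds that of each other library. They held 0.107% of that library's counts, with a median expected count of 2, but 160 of them reached at least 1 CPM and the highest reached 57.3 CPM. With an expected count of at least 5 required, the numbers were 509 in Ri replicate 1 and 18, 14 and 29 in the others. A greater depth is argued against, because Ri replicate 1 had the lowest total, 10077854 expected counts. An even background over all genes, as traces of genomic DNA would give, may be considered next. Among 4061 near-silent genes (1 to 3 counts over the other 3 libraries) the variance of its counts was 3.65 times the mean expected from length (95% bootstrap interval 3.20 to 4.06, the top 5% of genes left out), where 3 was the bound set for an even background, and 52.5% of these genes were at 0 where 38.4% were expected. The same ratio was 1.74, 1.67 and 2.04 in WT replicate 1, WT replicate 2 and Ri replicate 2, each over its own near-silent genes. Mean counts in these genes were 0.520, 0.398 and 0.738, against 2.37 in Ri replicate 1. The bound of 3 took no account of the mean, so for low-count genes an even background stays undecided. An even background would, however, give 18.4 of the genes at 1 CPM or more, not 160. An uneven background, RNA from other cells or tissue in that sample, and a difference between the plants stay open, since marker genes could not be named. Ri replicate 2 has the same genotype and did not show the excess, and no biological explanation was tested.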

How the results depend on the processing

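The 40 calls, all decreases, kept their negative sign in all 20 alternatives, but their number did not hold. The sign was all but fixed in advance, since both Ri values lay below both WT values in each of the 40 genes. The stricter threshold and the 2-fold requirement also reuse the main fit. With DESeq2 size factors edgeR called 48 genes (1 higher, Glyma.16G211200.Wm82.a2.v1) and with the length trend removed 42, close to the 40, and requiring a 2-fold change left 40. It called 12 with upper-quartile factors, 14 with the stricter filter, 13 without robust estimation and 164 (14 higher) without a filter; DESeq2's own test called 301 (36 higher). The count was 0 with library totals only (2131 genes at an unadjusted p under 0.05) and at an adjusted p of 0.01 in edgeR, where the smallest adjusted p was 0.0292. It was also 0 in limma-voom (2069 genes at an unadjusted p under 0.05), with limma on log2(FPKM + 1) (2182), on log2(FPKM + 0.1) (2131) and on unfiltered FPKM (2695). The cause of these moves was not tested. With the replicate number as a block edgeR called 107 genes (13 higher), 39 of them among the 40; the replicate numbers were not taken as pairs, since the differences between replicates 1 and 2 in WT and in Ri had a correlation across genes of -0.21; in simulated data the same replicate block called 112 unchanged genes where the fit without it called 18. A crossed replicate block, chosen after seeing the negative correlation of the numbers, called 68 (5 higher), 32 of them among the 40; both named increases passed under both blocks. Leaving out 1 library gave 0 to 1994 calls. For the 4 named genes no fold change turned sign in 72 values, as was all but fixed by replicate values that do not overlap. The 2 decreases passed in 11 of 18 alternatives each, and the increases of Glyma.16G211200.Wm82.a2.v1 and Glyma.18G227000.Wm82.a2.v1 passed in 7 and 6. These passes include the fits with a Ri library left out, which take their spread from the WT libraries. With all 4 libraries the adjusted p of both decreases was at most 0.139, in limma on unfiltered log2(FPKM + 1). The excess on chromosome 2, tested in 12 alternatives chosen after seeing the data, stayed past its threshold in 9 of them and not with either Ri library left out or under the crossed block. The calls of those 12 alternatives overlap with the 40, so the passes on chromosome 2 are not separate evidence. Calls in both directions were counted together there. The genes listed in 1 genotype only numbered 23 and 16 when 0.5 CPM was required, and 4 and 4 at 2 CPM. The 35 gene lists were not run under any setting, since the identifiers could not be tied to product names. Depth limits genes below about 0.3 CPM, and with 2 libraries per genotype decreases of 2-fold were recovered for 3 of 33 simulated genes.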

Other observations

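The tests of scaling, of single libraries, of chromosome 2 and of the WT replicates were chosen after the results were seen. The tests of gene length and of other splits of the libraries were written before theirs.

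The genes that fell in Ri also differed together between the WT replicates. WT replicate 1 was higher than WT replicate 2 in 34 of the 40, with a median log2 difference of 0.32. This lay at percentile 100 of 10000 random lists matched on mean expression, whose central 95% ran from -0.10 to 0.13. Between the Ri replicates the median difference was 0.05, at percentile 74.4. A hypothesis is that the called genes form a set that varies together between plants, but it stays undecided: the WT pair shows such a difference and the Ri pair does not, each is 1 pair of libraries, and the 40 genes were chosen from the same libraries.

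All 40 calls were decreases. A scaling error no larger than the differences between 4 scalings is argued against as the source of the excess of genes more than 2-fold lower. To bring them and those more than 2-fold higher to equal numbers, both Ri libraries would have to be raised by 0.25 on the log2 scale over all tested genes (421 lower, 159 higher) and by 0.46 among genes of at least 8 CPM (174 and 17). The median change of all genes moved by at most 0.03 between 4 scalings. An error shared by all 4, which start from the same counts, is not bounded by this. After removal of a length trend the median log2 change of the 40 genes was -3.21 (SD 0.83). The 40 were chosen as decreases in the same libraries, so a median near 0 was unlikely and this value decides little. The fit without the trend chose its genes anew and called 42, all lower, which argues against a length trend as the source of the one-sided calls. A single aberrant library as the source of the decreases is also argued against, since at least 54.7% of decreases chosen in 1 pair of libraries recurred in the other. Whether the lack of increases among the calls rests on a single library stays undecided. Without Ri replicate 1, 1151 of 1994 calls (57.7%) were higher, and without Ri replicate 2, 634 of 1623 (39.1%), and on simulated counts the fit without Ri replicate 1 called 83 unchanged genes where the fit with all libraries called 18. Each of these fits holds 1 Ri library and takes its spread from the WT libraries, which differed less from each other (SD of the log2 difference 0.31) than the Ri libraries did (0.59), so that library's own deviations count as genotype. The 3 splits of the libraries are too few for a share under 0.05: 1 of the 3, the real one, gave 40 edgeR calls and the highest of the others gave 0. The split of WT replicate 1 and Ri replicate 2 against the others gave 2667 genes at an unadjusted p under 0.05 where the real split gave 2135. Whether this reflects a structure of the samples other than genotype was not tested. For the decreases, suppression of GmHAD1-2 itself and any other difference between the transgenic and wild-type plants stay open, and this design does not separate them.

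The excess of calls on chromosome 2 was weighed against 1 shared chromosome segment, such as a stretch of another parent's chromosome. At most 3 of the 8 genes lay within 100 neighbouring tested genes of that chromosome, at most 4 within 300 and at most 5 within 600, and all 8 spanned 1598 of its 1927 tested genes. The answer depends on the length allowed for a segment, which the data do not give, so a segment behind part of the 8 genes stays open.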
